A study of Mus musculus with 2 samples.

How the data were processed

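EP300 was measured by chromatin immunoprecipitation and sequencing in stomach of newborn mice, in 2 libraries that form 1 group. The deposited files are 5 peak lists in narrowPeak layout on mm10, for replicate 1, replicate 2, the pooled reads, and the optimal and conservative IDR sets. The unit of peak strength is the signal value of the authors' peak caller, which stands on a scale of its own in each list and is not normalized between lists. The deposited lists also carry a score: the IDR sets hold a scaled IDR score of up to 1000, and the q column of every list was kept as a score because in some lists it reaches slightly below 0. The deposited summit position is given as an offset in bp from the peak start, counting from 0, a unit of the layout other than signal or score. The peak caller, its version and the aligner are not given in the sources used here. The readme texts name the input of each list. The list of replicate 1 came from its alignment and a further file, and that of replicate 2 from its alignment and a pair of further files, of which 1 also stood behind the list of replicate 1. The pooled list came from both alignments and that pair, and the IDR sets from the pooled list, both replicate lists and a further file of unstated content. The labels name possible controls, but not which list used which.

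No read counts are in the files, so depth is unknown and no interval that needs it is given. Each of the replicate and pooled lists ends at 300000 peaks, so their lengths say nothing of depth. Intervals of shares are exact (Clopper-Pearson) 95% binomial intervals. The signal of a peak is given for each library where a peak of that library's list has its summit inside it, with no test between libraries. Of several such peaks the strongest was taken. Overlapping optimal peaks can share the same peak of a library's list.

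Coordinates are 1-based and inclusive, on mm10. Genes, transcripts and exons came from GENCODE release M21, with 21911 protein-coding genes, and sequence from the matching assembly. Of the 7737 optimal peaks, 4 lay off the named chromosomes and were left out of all analyses of position, leaving 7733. A promoter peak had its summit within 1 kb of a protein-coding transcript start, a distal peak over 10 kb from any, and the rest were called intermediate. Features of summits came from protein-coding genes alone, so a summit called intergenic can lie in a non-coding gene. A narrow peak is narrower than the full width of its list. The optimal list holds overlapping peaks, and 7732 distinct intervals; each listed peak was counted, and runs of overlapping peaks are called regions.

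The comparisons and tests were as follows. Replicates were compared by the overlap, by at least 1 bp, of as many strongest peaks of each list as the optimal set holds, beside 100 random placements, and by Pearson and Spearman correlation across matched optimal peaks. The IDR sets were compared by shared peaks and by a two-sided permutation test of median log2 signal with 100000 permutations, which was also used for promoter against distal peaks. The promoter share was set against 100 random placements outside assembly gaps by Fisher's exact test. For each of 22 gene lists, genes with a summit within 50 kb of their start were counted and compared with all other protein-coding genes by a two-sided Fisher's exact test. Such a summit can lie nearer to the start of another gene, and neighbouring genes can share summits. The log2 odds ratios and log2 ratios have 0.5 added to each count. For 31 consensus motifs, the share of summits with the motif on either strand within 100 bp was compared with a window centred 1000 bp away by an exact McNemar test, and promoter with distal summits by Fisher's exact test. The ratio to dinucleotide-shuffled sequence was tested by a normal test of the log ratio. P-values were adjusted by Benjamini-Hochberg over the 22 lists or the 31 motifs, with a threshold of 0.05. The lists, motifs, tests and most alternatives were fixed before the data were examined. The symbols Cblif, Loricrin and Amy2b were not in the annotation and were dropped.

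Genes were named by a fixed rule: the nearest protein-coding gene of each of the 20 strongest optimal peaks, the 10 genes with the most optimal summits within 50 kb, up to 4 members of each list with the most summits, and the 8 motifs with the highest ratio past the threshold. Genes without a summit, further motifs, the genes of the X chromosome, Carmn, Mir143 and Mir145a, and the genes of the peak clusters fall outside that rule and were chosen after their values were seen. Values of a few genes that the rule names are not reported here.

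The alternative settings fixed beforehand were the conservative set, the stronger part of the optimal set, the strongest peaks of each replicate list alone and of the pooled list, other overlap criteria, other distances and windows, assignment to the nearest start, distal summits only, linked genes within 100 kb counted as 1 locus, 10000 matched random gene lists, and other motif windows and controls. Added after the data were seen were merging of overlapping peaks, leaving out narrow peaks, the pooled list as background for the promoter share, leaving the smooth muscle or the squamous list out of the stomach genes, and counting each pair of replicate peaks once in the ranking by summed ranks.

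The tests were tested on simulated data. Of simulated gene lists with an odds ratio of 6, 98% were called, and of random lists 3%. All 31 motifs were called when planted in 5% of 4000 windows, and 0 with none planted. Most of the 8 motifs named below were rarer than that at summits, so recovery at their shares was not tested. Both simulated sets were shuffles of the same summit windows. False calls from a difference in composition, such as 51.9% GC at summits and 46.3% in flanks, were thus not tested. The overlap call differed from a direct count on 0 of 300 intervals. The permutation test called 6 of 100 pairs of groups with no difference and 98 of 100 shifted pairs. Planting in 10% of the windows of 1 class gave 31 motif differences called by unadjusted p, and with none planted 1 was called by adjusted p. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9.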

Results

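EP300, a histone acetyltransferase and transcriptional co-activator, was mapped by chromatin immunoprecipitation and sequencing in whole stomach of newborn mice (postnatal day 0, strain B6NCrl). The series holds 2 libraries in 1 group, and no library from another tissue or stage, so the comparisons lie between the replicates, between classes of peaks and between groups of genes. The libraries are labelled as biological replicates 1 and 2, but both carry the same biosample and donor label, so the spread between them need not include a difference between animals. The sex of the animals was not collected. The files give peak lists without read counts, so the depth of each library is unknown. The lists of replicate 1, of replicate 2 and of the pooled reads each held 300000 peaks. The optimal set, which the authors kept by the irreproducible discovery rate (IDR), held 7737 peaks in 6082 separate regions, and the conservative IDR set held 6974 peaks in 5491 regions. The median signal of the optimal peaks was 30.2 (quartiles 23.7 and 39.6), within a range from 7.68 to 506.3. Intervals given with shares are exact 95% binomial intervals, which cover counting error only, and peaks of a list are not independent replicates.

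Of the 20 strongest EP300 peaks, 19 lay at promoters. The peak with the highest signal lay 361 bp from the start of Cdk12, a kinase of transcription elongation (mm10 chromosome 11, 98202416 to 98202909, intergenic), with a signal of 506.3 in the pooled reads, 251.0 in replicate 1 and 267.9 in replicate 2. Next came a peak on a UTR exon of Wdr77, a partner of the arginine methyltransferase PRMT5 (chromosome 3, 105959124 to 105959568, signal 485.9), and a peak on a UTR exon of Denr, a translation factor (chromosome 5, 123907038 to 123907431, signal 468.0). The other 17 of the 20 strongest peaks were nearest to Psmd5, Qrich1, Ube2d3, Rbm39, Mapk14, Mdh2, Rraga, Fubp1, Ostc, Minos1, Ercc6l2, Dync1h1, Eif4a3, Naa38, Tmem18, Riok2 and Ddx20. They include a proteasome assembly factor (Psmd5), a ubiquitin-conjugating enzyme (Ube2d3), the stress kinase p38 alpha (Mapk14), mitochondrial malate dehydrogenase (Mdh2) and an RNA helicase of the exon junction complex (Eif4a3). A promoter peak here has its summit within 1 kb of a protein-coding start, and the exception lay 9817 bp from that of Dync1h1. All 20 were in the conservative set, and none ranked below 23 in replicate 1 or below 21 in replicate 2. All 20 were also narrower than the full width of 560 bp shared by most optimal peaks (287 to 494 bp, median 387 bp). In the whole optimal set 157 peaks were narrower than 560 bp. Their median signal was 168.5, against 29.9 for the other peaks, and 137 of them lay at promoters.

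Promoters held 2952 of the 7733 optimal summits on named chromosomes (38.2%, interval 37.1 to 39.3), counting summits within 1 kb of a protein-coding start. A further 1322 summits (17.1%) lay between 1 and 10 kb from such a start, and 3459 (44.7%) were distal, with a median distance of 42835 bp. By annotation of protein-coding genes alone, 3789 summits (49.0%) were intergenic, that is outside any such gene, and 2855 (36.9%) were in introns. UTR exons held 906 (11.7%) and coding exons 183 (2.37%). Random placements on the same chromosomes put 2.68% of positions at promoters (2.12 to 3.14% over 100 placements), so the observed share was 14.2-fold higher. Among the 290152 peaks of the pooled list outside the optimal set the promoter share was 4.57%. In this comparison, added after the data were seen, the optimal share was 8.36-fold higher. Fisher's exact test gave a two-sided p too small to be held as a number in both cases.

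Promoter peaks were only slightly stronger than distal peaks. The median signal was 32.1 at promoters (quartiles 23.8 and 45.2, n = 2952) and 29.5 at distal sites (quartiles 23.8 and 37.3, n = 3459), a 1.09-fold difference (0.12 on the log2 scale). The two-sided permutation test of the medians gave p = 1e-05, the smallest that 100000 permutations can give. Without the narrow peaks, the log2 difference was 0.08.

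In the optimal set the gene with the most EP300 summits within 50 kb of its start was Il17b, a member of the interleukin-17 family (chromosome 18, 61684887 to 61692538), with 23 summits in 12 regions. The strongest of them within that window lay outside protein-coding genes, 31423 bp from the start (61653184 to 61653743, signal 61.7). Peaks of this group ran upstream across Carmn, a long non-coding RNA, and across Mir143 and Mir145a, microRNAs known from smooth muscle; these 3 genes were singled out after their values were seen. The next genes formed a single neighbourhood on chromosome 11, with 18 summits for Vamp2, 16 for Per1, 16 for Tmem107, 15 for Borcs6, 13 for Hes7 and 13 for Aurkb. Its strongest peak lay in an intron of Per1, a component of the circadian clock (69096916 to 69097192, signal 176.9). Asna1 on chromosome 8 had 13 summits, and 7 histone genes on chromosome 13 tied at 12, of which the rule for ties picks Hist1h2ad and Hist1h3f. Neighbouring genes share these summits, so the counts are not independent of each other. Counts per gene, here and below, depended on the peaks taken: Il17b had 15 summits in the strongest peaks of replicate 2 alone, 10 in those of replicate 1 alone and 12 in the conservative set, and in the last of these settings and in replicate 1 alone Vamp2 had more (17 and 15). Ier3, below with 11, had 4, 5 and 3 in the same settings.

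**Figure D1:**
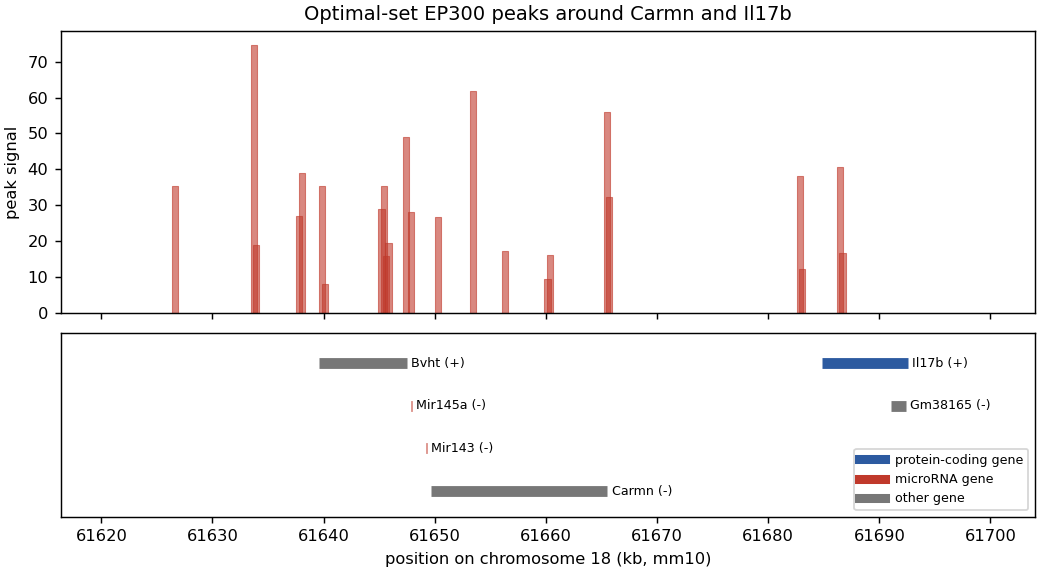
Optimal-set EP300 peaks around Carmn and Il17b on mm10 chromosome 18, by position (kb) on the x axis and signal in the pooled reads on the y axis, each bar spanning a peak, with annotated genes and their strands drawn below. Of the 23 summits within 50 kb of the Il17b start, the strongest had a signal of 61.7, and a peak beyond that window reached 74.7.

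Smooth muscle genes had EP300 summits nearby more often than other genes, in a test over 22 gene lists fixed before the data were examined. Of the 24 contractile and structural genes of smooth muscle, 21 had an EP300 summit within 50 kb of their start (87.5%, interval 67.6 to 97.3), against 7652 of all 21911 protein-coding genes (34.9%). Acta2, smooth muscle alpha actin, had 4 summits, the strongest 10197 bp from its start (chromosome 19, 34265507 to 34266066, intergenic, signal 52.9). Tpm2, a tropomyosin, had 4 (strongest signal 42.7, 184 bp from the start), Smtn had 3 (50.7, in an intron of the gene) and Actg2, enteric gamma actin, had 3, the strongest of which (66.1) was nearest to the start of Dguok. Des, Kcnmb1 and Synpo2 had none. The log2 odds ratio was 3.52 (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 3.31e-06 over the lists).

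Immediate early genes also had summits more often than other genes. Of 20 such genes, which respond first to growth factors and stress, 17 had a summit within 50 kb (85.0%, interval 62.1 to 96.8, log2 odds ratio 3.22, adjusted exact p = 6.41e-05). Btg2 had 11 summits (strongest signal 63.3), Ier3 had 11 (36.0), Zfp36 had 10 (217.3, at a peak nearest to Supt5) and Klf6 had 9 (113.0). Egr1, Egr2 and Egr3 had none. The order of the lists depended on the settings: among the 3867 strongest peaks the log2 odds ratio was 1.97 for smooth muscle and 3.83 for immediate early genes, and the latter was also the higher in the conservative set (2.83 and 3.33), replicate 2 alone (2.54 and 4.42), replicate 1 alone (2.84 and 3.54) and a 10 kb window (2.43 and 2.98).

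Ribosomal protein genes and squamous forestomach genes also had summits more often than other genes, with calls that depended on the settings. For ribosomal protein genes the count was 18 of 24 (75%, log2 odds ratio 2.41, adjusted exact p = 0.000773), with 5 summits each for Rps18 and Rpl18. For genes of the squamous epithelium that lines the mouse forestomach it was 17 of 25 (68.0%, log2 odds ratio 1.94, adjusted exact p = 0.00591). Krt13 and Krt15, keratins of stratified epithelium, had 6 and 5 summits. Sfn had 4 (strongest signal 112.9, at a peak nearest to Gpatch3), and Evpl, envoplakin of the cornified envelope, had 4. Krt5 and Trp63, markers of basal cells, had none, nor did Krt4, Krt6a, Dsc3, Sprr1a, Sprr3 and Tgm3. With the conservative set the ribosomal call ended (log2 odds ratio 1.47, adjusted exact p = 0.0833), and with promoter summits left out the ratio fell to 0.05 (adjusted p = 1). The squamous call ended with a 10 kb window (1.12, adjusted exact p = 0.198) and with each summit given only to its nearest start (1.27, adjusted p = 0.0783).

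The other lists of stomach cell types did not pass the test. Transcription factors of the gastric epithelium had a summit for 5 of 24 genes (adjusted exact p = 0.397), among them Grhl2 and Foxq1 with 5 summits each, Klf5 with 3 and Ehf with 2. Gata4, Foxa2, Hnf4a and Sox2 had none; genes without a summit are named here and above after their values were seen. Transcription factors of the gastric mesenchyme had a summit for 8 of 26 (adjusted exact p = 0.970), with 3 summits each for Pitx1 and Nr2f2 and 2 each for Meis1 and Nfia. Secretory and surface genes of the glandular stomach had a summit for 6 of 23 (adjusted exact p = 0.704), with 3 summits for Psca and 1 each for Gkn1, Gkn2 and Kcne2, and none for Atp4a and Atp4b, the acid pump of parietal cells. Gkn1 and Gkn2 shared the same summit, which was nearest to Antxr1. Gastric endocrine genes had a summit for 3 of 20 (adjusted exact p = 0.176), these being Gast, Ghrl and Mboat4 with 3 summits each. Their strongest peaks were nearest to Krt42, Tatdn2 and Dctn6, in this order. The counts were 8 of 22 for fibroblast and matrix genes (adjusted exact p = 1), 6 of 20 for endothelial genes (adjusted p = 0.970), 5 of 20 for enteric neuron and glia genes (adjusted p = 0.704) and 3 of 20 for blood and immune genes (adjusted p = 0.176). Named members of these were Col5a1 and Col1a2 with 3 summits each, Cldn5 and Egfl7 with 2 each, Erbb3 with 8 and Fcgr1 with 3. The strongest peaks counted for Psca, Cldn5, Erbb3 and Fcgr1 were nearest to the start of another gene. In the strongest peaks of replicate 2 alone and of replicate 1 alone, the counts were 8 and 9 for the epithelial factors, 10 and 13 for the mesenchymal factors, 3 and 5 for endocrine genes and 8 and 6 for blood and immune genes, and none of these passed the test. With each summit given only to its nearest start, the log2 odds ratio of the epithelial factors turned from -0.93 to 1.36 and that of the mesenchymal factors from -0.22 to 1.41 (adjusted exact p = 0.0747 and 0.0610).

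Among signalling pathways, BMP and TGF-beta genes had a summit for 10 of 23 (adjusted exact p = 0.611), led by Id1 with 8 summits and by Id3, Smad7 and Id2 with 3 each. Wnt pathway genes had a summit for 11 of 24 (adjusted exact p = 0.485), led by Wnt4 and Znrf3 with 3 summits and by Axin2 and Nkd1 with 2. Of the hedgehog pathway genes, 1 of 14 had a summit (adjusted exact p = 0.164), this being Ptch1, the hedgehog receptor, with 6. With each summit given only to its nearest start, the BMP and TGF-beta list (log2 odds ratio 2.68, adjusted exact p = 9.91e-05) and the Wnt list (1.84, adjusted p = 0.0123) passed the threshold. The hedgehog count depended on the peaks taken, with 4 of 14 in the strongest peaks of replicate 2 alone, 5 in those of replicate 1 alone, 3 in the conservative set and 6 with nearest starts, where the log2 odds ratio turned from -2.27 to 1.68 (adjusted exact p = 0.0747).

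**Figure D2:**
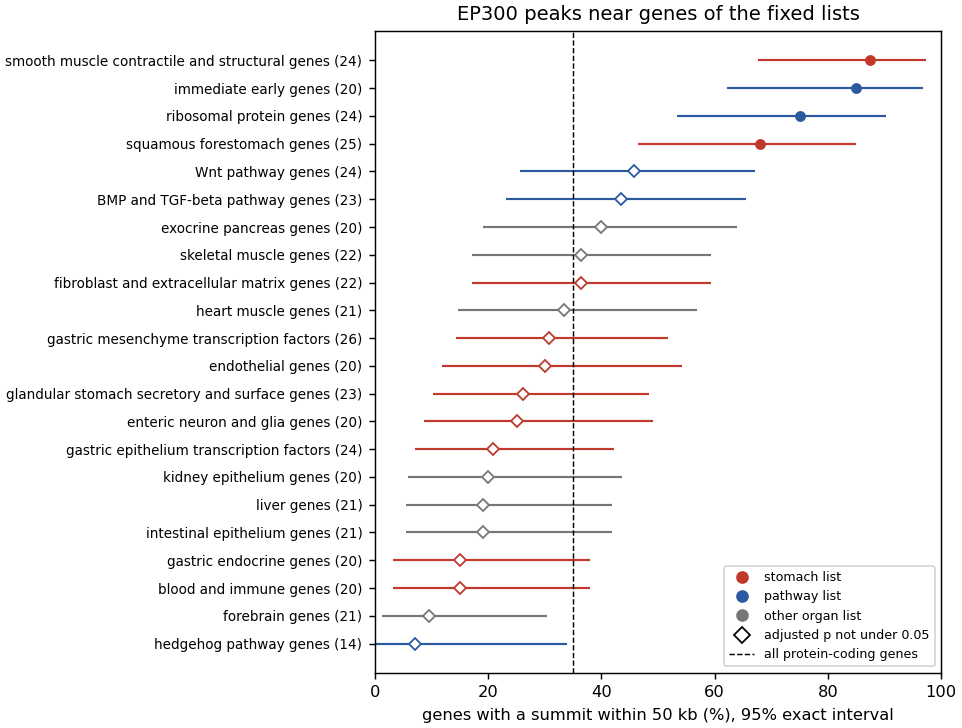
Share of the genes of each of the 22 lists with an optimal-set EP300 summit within 50 kb of the start, in percent, with exact 95% binomial intervals and the number of genes of each list in brackets; colour gives the kind of list, and filled points passed the threshold of 0.05. The dashed line marks the 34.9% of all protein-coding genes; smooth muscle genes (87.5%) and immediate early genes (85.0%) lie farthest to its right.

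Genes of stomach cell types had an EP300 summit within 50 kb more often than genes typical of other organs. The counts were 82 of 224 stomach genes (36.6%, interval 30.3 to 43.3) and 37 of 145 genes of other organs (25.5%, interval 18.6 to 33.4), with a log2 odds ratio of 0.74 (two-sided Fisher's exact test, p = 0.0302). The share over all protein-coding genes was 34.9%. The stomach share was thus close to that of all genes, and the contrast lay mainly in the lower share of other organs. Of the other organs, intestinal epithelium had 4 of 21 genes with a summit (adjusted exact p = 0.373), liver 4 of 21 (adjusted p = 0.373), exocrine pancreas 8 of 20 (adjusted p = 0.833), heart muscle 7 of 21 (adjusted p = 1), skeletal muscle 8 of 22 (adjusted p = 1), forebrain 2 of 21 (adjusted p = 0.0518) and kidney epithelium 4 of 20 (adjusted p = 0.439). The forebrain list passed the threshold, with fewer summits than other genes, for a 100 kb window (log2 odds ratio -2.35, adjusted exact p = 0.00845) and for the strongest pooled peaks (-2.27, adjusted p = 0.0261). In the strongest peaks of replicate 2 alone and of replicate 1 alone its count was 5 and 3, and that of the liver list 6 and 7. Within 10 kb the contrast was larger, at 36 of 224 against 4 of 145 (log2 odds ratio 2.61, exact p = 2.45e-05). The contrast at 50 kb rested on the smooth muscle and squamous lists. Without the former the stomach count was 61 of 200 (30.5%, log2 odds ratio 0.35, exact p = 0.335), and without the latter 65 of 199 (32.7%, 0.49, p = 0.188), both added after the data were seen. The contrast also missed the threshold among the 3867 strongest peaks (0.70, exact p = 0.0616) and with linked genes counted as 1 locus (0.64, p = 0.0726).

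Binding motifs of ETS, grainyhead, KLF and SP, and AP-1 factors were more frequent at EP300 summits than in flanks 1000 bp away. Of the 31 motifs tested, 17 were more frequent within 100 bp of the summit and 2 less frequent. The 8 with the highest ratios were ETS (9.80-fold, 0.634% of summits, adjusted exact p = 1.72e-09), GRHL (7.20-fold, 0.466%, 2.03e-06), NRF1 (7.0-fold, 0.181%, 0.00682), CTCF (5.71-fold, 0.517%, 1.68e-06), CRE (5.25-fold, 0.815%, 6.56e-09), CEBP (4.75-fold, 0.246%, 0.00448), KLF and SP (4.27-fold, 7.51%, 2.15e-68) and AP-1 (2.57-fold, 9.74%, 3.80e-49). AP-1 and KLF and SP sites were thus at 753 and 581 of the 7733 summits, and the others of the 8 at between 14 and 63. TEAD sites were 1.85-fold, MEF2 sites 2.24-fold and the CArG box of SRF 1.51-fold more frequent at summits (adjusted exact p = 8.39e-23, 0.000431 and 0.00448). The E-box CATATG (0.454-fold, adjusted exact p = 1.86e-19) and the homeobox motif (0.725-fold, adjusted p = 3.46e-05) were less frequent. These p-values are from exact McNemar tests, two-sided, adjusted over the 31 motifs. Base composition differed, with 51.9% GC at summits and 46.3% in flanks. Against shuffled sequence of the same dinucleotides no motif was called less frequent: the E-box CATATG (log2 ratio 0.02) lost its call and the homeobox motif (0.40) was more frequent, while CEBP (0.08), NF-Y (0.10) and the shorter NFI motif TTGGCNNNNNNCCA (0.40) were not called. CEBP also lost its call in the conservative set, the 3867 strongest peaks and replicate 2 alone (log2 ratios 1.49, 2.07 and 1.04), NRF1 within 50 bp of the summit, in the 3867 strongest peaks and in replicate 2 alone (3.17, 1.93 and 1.35), and the CArG box within 50 bp, in the 3867 strongest peaks and in replicate 1 alone (0.61, 0.41 and 0.23).

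Promoter and distal EP300 summits differed in their motifs. AP-1 sites were at 14.5% of distal and 3.39% of promoter summits (adjusted exact p = 1.71e-55), FOX sites at 10.6% and 4.17% (adjusted p = 3.18e-22) and TEAD sites at 10.5% and 4.98% (adjusted p = 1.18e-15). At promoters the shares were higher for NF-Y (14.2% against 5.98%, adjusted exact p = 3.81e-27), KLF and SP (11.5% against 4.19%, adjusted p = 2.97e-27) and the strict ETS motif (1.46% against 0.116%, adjusted p = 1.93e-10). Of 31 motifs, 6 were more frequent at promoters and 17 at distal summits (two-sided Fisher's exact test). When each share was taken relative to shuffled sequence of the same dinucleotides, 3 differences passed the threshold, in NF-Y and the ETS core at promoters and AP-1 at distal summits. The KLF and SP difference then turned direction (log2 -0.52), and FOX (-0.28), TEAD (-0.61) and the strict ETS motif (0.95) lost their calls. Among the other calls at distal summits, STAT was lost in all 6 other peak sets (adjusted exact p = 0.143 to 1), HNF1 in all of them but the conservative set (0.0502 to 0.330), and GRHL in the conservative set and in replicate 2 alone (0.0615 and 0.0594).

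**Figure D3:**
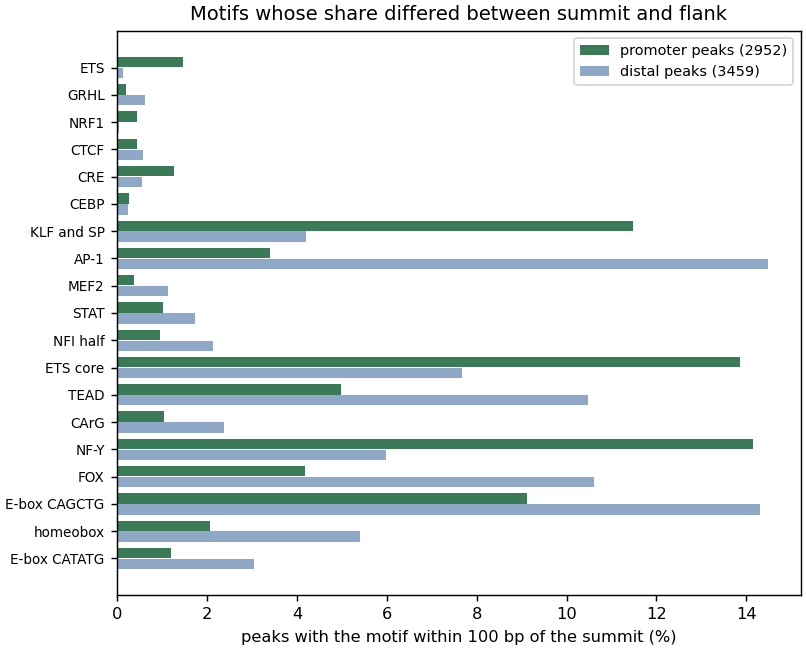
Share of promoter and of distal optimal-set EP300 summits with each motif within 100 bp, in percent, for the 19 motifs whose share differed between summit and flank; bars start at 0 and show shares without error bars. AP-1 was at 14.5% of distal and 3.39% of promoter summits.

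The replicates ranked the 20 strongest peaks alike and the optimal peaks as a whole less so. The Wdr77 and Cdk12 peaks ranked 1 and 2 in replicate 1, and 2 and 1 in replicate 2. Some single genes differed more: the strongest peak at Tpm2 had a signal of 35.3 in replicate 1 and 13.9 in replicate 2, and that at Nfia 6.91 and 23.6, each on its own list's scale. Of the 7737 strongest peaks of replicate 1, 3634 overlapped a peak among the 7737 strongest of replicate 2 (47.0%, interval 45.9 to 48.1), and in reverse 3578 did (46.2%). Random placement gave 0.363% (0.168 to 0.556% over 100 placements). Across the 6868 optimal peaks matched in both lists (88.8%), the correlation of log2 signal was 0.52 by Pearson and the rank correlation was 0.37 by Spearman; this is across peaks, so no p is given. The rank correlation was 0.54 over 2590 promoter peaks and 0.23 over 3119 distal peaks, a difference that was not tested. Distal peaks were matched in both lists slightly more often (90.2% against 87.7%). Their pooled signals spanned a narrower range (quartiles 23.8 and 37.3, against 23.8 and 45.2 at promoters), which can lower a correlation. Of the optimal peaks, 3315 (42.8%) held summits of the 7737 strongest peaks of each replicate list. No test between single libraries is possible, and the lists were not made alike, since the list of replicate 2 was derived with a further file that the list of replicate 1 lacked.

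**Figure D4:**
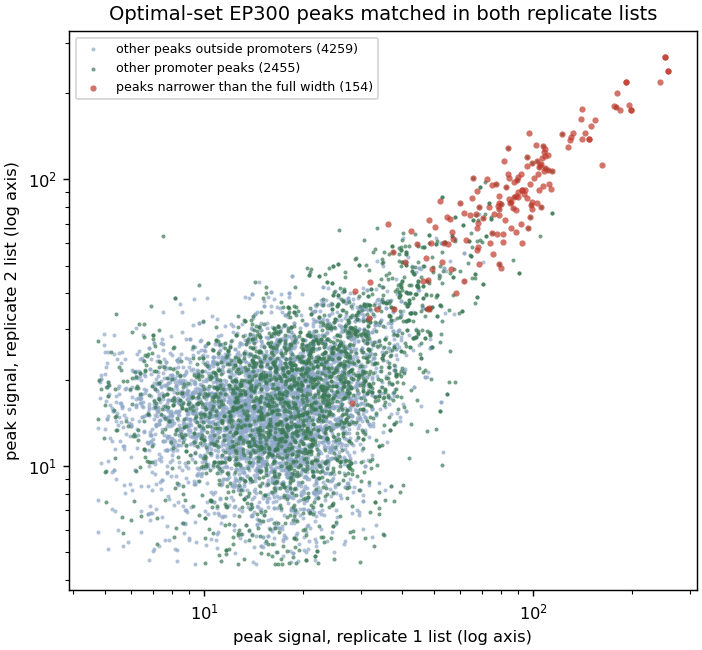
Signal of each matched optimal peak in replicate 1 (x axis) and replicate 2 (y axis), both on log scales and each on its own list's scale, with promoter peaks in green, peaks outside promoters in blue and the 154 matched narrow peaks in red. Across the 6868 matched peaks the Pearson correlation of log2 signal was 0.52.

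Optimal peaks that were also in the conservative set were stronger than those that were not, and included all 20 of the strongest, from Cdk12 to Ddx20. The sets overlapped in 5390 of the optimal peaks (69.7%) and 5354 of the conservative peaks (76.8%), so 1620 conservative peaks had no counterpart in the optimal set. The median signal was 34.3 for shared optimal peaks and 24.8 for the 2347 others, a 1.38-fold difference (0.47 on the log2 scale, two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Both sets were thresholded by IDR from the same lists, so stronger peaks may be shared through that selection alone. The p describes these lists, whose peaks are not independent replicates. The strongest peaks near Nfia, Col5a1 and Psca were among those in the optimal set only.

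The X chromosome held few of the optimal EP300 peaks. It carried 70 of 7733 optimal peaks (0.905%, interval 0.706 to 1.14), with 6.28% of the assembled length and 4.33% of the protein-coding genes. The strongest lay at the promoters of Huwe1, a ubiquitin ligase (151803179 to 151803318, intron, signal 147.5), and Tab3 (85573743 to 85573884, intergenic, signal 95.3), genes picked after their values were seen. Per protein-coding gene there were 0.0738 peaks on the X and between 0.271 (chromosome 7) and 0.50 (chromosome 18) on the autosomes. The whole pooled list held few X peaks too, with 44.9 per Mb on the X and at least 94.3 on each autosome, and 8.10 per coding gene, below every autosome but chromosome 7 (6.79). Per Mb the X held 0.379 times as many peaks as the autosomes in the pooled list and 0.132 times as many in the optimal set. No peak lay on the Y chromosome in any of the 5 lists.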

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

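The alternatives with merged peaks, without narrow peaks, with the pooled list as background, without the smooth muscle or the squamous list, and with each pair of replicate peaks counted once were chosen after the data were seen. The smooth muscle and immediate early calls held under each alternative run, with log2 odds ratios of 1.97 to 4.08 and of 2.94 to 4.42; the promoter share (33.1 to 44.5%) and the signal differences kept direction and call. Replicate overlap was 41.8% at 50% reciprocal overlap, 31.5% with summits within 100 bp, 49.9% for the 3868 strongest peaks and 31.5% for 5 times as many peaks as in the optimal set. The rank correlation was 0.39 in the conservative set, 0.40 over all matched peaks and 0.35 with overlapping peaks merged. The contrast of stomach genes with genes of other organs (log2 odds ratio 0.74) missed the threshold at 0.70 among the stronger peaks, 0.64 with linked loci, 0.35 without smooth muscle genes and 0.49 without squamous genes. With a single replicate list it was 0.78 to 1.05. Against dinucleotide-shuffled sequence the direction turned for E-box CATATG (0.024), homeobox (0.40) and PBX and MEIS (2.81), and the motif differences between promoter and distal summits called fell from 23 to 3, with signs turned for CRE (-0.28), GATA (0.015), KLF and SP (-0.52), MEIS (0.19), the nuclear receptor site RAGGTCA (0.18), STAT (0.12) and MEF2 (0.29). None of these turned differences between promoter and distal summits passed the threshold. Among the strongest peaks of replicate 2 alone the full NFI palindrome passed the threshold (2.66), and the nuclear receptor site was less frequent than in flanks there (-0.29) and among those of replicate 1 alone (-0.25). Summit counts of the 111 named genes moved over 1.5 times for 30 genes in replicate 2 alone, 39 in replicate 1 alone, 26 in the conservative set, 18 among the strongest pooled peaks, 29 with merged peaks and 53 among the stronger peaks. Ranking by summed replicate ranks kept 15 of the 20 strongest peaks, because 5 weaker optimal peaks share the replicate peaks of stronger ones; with each pair of replicate peaks counted once, all 20 were kept. The cause of these changes was not tested, except that leaving out a list leaves fewer genes. Unknown depth limits any statement that a site lacks EP300.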

Other observations

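The tests on the X chromosome and the count of peak clusters were chosen after the data were seen; the other tests reported here were written before their results. Stitching the 4781 optimal peaks over 1 kb from a coding start at distances of up to 10 kb gave 3464 clusters, of which 3113 held 1 region and 7 held at least 5. The cluster with the most regions covered 39600 bp of chromosome 18 (61626371 to 61665970), with 20 peaks in 11 regions and signals of up to 74.7, and spanned the long non-coding RNAs Bvht and Carmn and the microRNA genes Mir145a and Mir143. Zbtb16, a zinc finger transcription factor, held 5 regions with signals of up to 179.1 (chromosome 9, 48723574 to 48740390). Neighbouring clusters of 5 regions lay at the long non-coding RNAs Neat1 (signals of up to 96.3) and Malat1 (up to 125.5). Further clusters of 4 regions lay across Chit1 upstream of Btg2 (up to 63.3), at Id1, a target of BMP signalling (up to 65.5), near Junb (up to 40.6) and at Nr1d1, a repressor of the circadian clock (up to 34.5).

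Motifs near the gene lists were tested as hypotheses of regulation. CArG boxes, the sites of SRF, were at 4 of the 45 optimal summits within 50 kb of smooth muscle genes (8.89%) and at 1.73% of all others, an odds ratio of 5.54 (interval 1.42 to 15.6, Fisher's exact test, p = 0.00801). These summits lay at the promoters of Actg2 and Tagln, 10197 bp from Acta2 and in an intron of Pcsk7 near Tagln. SRF may thus take part in EP300 binding there, a hypothesis that rests on 4 sites. The comparison was with other EP300 peaks and not with unbound sequence near the same genes. It cannot tell whether CArG boxes are frequent near these genes regardless of EP300. Over all peaks the CArG box was not called among the strongest peaks of replicate 1 alone (log2 ratio 0.23). It also lost its call within 50 bp of the summit and among the 3867 strongest peaks. Near immediate early genes, CArG boxes or CREs were at 3 summits (2.97%, odds ratio 1.16, interval 0.232 to 3.53, exact p = 0.747). Near squamous genes, AP-1 or GRHL sites were at 5 of 39 summits (odds ratio 1.31, interval 0.398 to 3.37, exact p = 0.590). Both intervals are too wide to tell more sites from none.

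Of the 157 strongest optimal peaks, 126 were among the 157 narrow peaks. The palindrome TCTCGCGAGA, with at most 1 mismatch, was within 100 bp of the summit in 71.3% of the narrow peaks (interval 63.6 to 78.3), against 6.15% of other promoter peaks, and in 18 of the 20 strongest. They were not peculiar to a library, since 98.1% were among the strongest of both replicate lists (154 of 157, interval 94.5 to 99.6). The share of repeat bases at their summits differed from that at other promoter summits by -0.902 percentage points (interval -2.36 to 0.555), which leaves a small part for repeats open. The palindrome passed the bar of over 50% written beforehand, so a factor that binds it may account for most of these peaks, although no such factor was measured. With a single group, no biological explanation that needs a comparison of groups was tested.

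Each optimal peak took the rank of the strongest pooled-list summit inside it, and for 1324 peaks that rank lay beyond the size of the optimal set. A weak peak with a stronger summit inside it took the rank of that summit and was not counted. By their own signal more optimal peaks were weak, since their lower quartile (23.7) was below the pooled signal at rank 7737 (24.2). If the 1324 were shoulders of stronger peaks, most should have lain within 560 bp of a stronger optimal summit. Of them 36.7% did (485 of 1323 on named chromosomes, interval 34.1 to 39.3), against 18.0% of the other optimal peaks. Only stronger summits were counted, and a weak peak has more of these to lie near, so the test itself sets part of that contrast. Shoulders of stronger optimal peaks may account for at most 36.7% of the 1324. The test cannot tell how many of all weak optimal peaks are shoulders, since those closest to a stronger summit were not among the 1324. How the authors' IDR step ranked peaks stays open, since the files do not give it.

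The X chromosome held fewer optimal peaks than its genes would give. A smaller number of genes is argued against, since peaks per coding gene were 0.200 times those of the autosomes (interval 0.156 to 0.253). If each cell held a single X copy and signal scaled with copies, the X should hold at least as many pooled-list peaks per coding gene above a signal of 24.2 as the autosomes hold above 2 times that signal; the ratio was 1.58 (interval 1.24 to 1.99, 79 X peaks and 1096 autosomal peaks). That bar had no upper limit. An X with no deficit would also have passed it, since the autosomes held 7654 peaks above 24.2. Signal scaled to a single copy would remove more peaks than are missing. The test thus cannot tell whether a single copy took part in the deficit. The sex of the animals, which was not collected, stays untested, and the empty Y chromosome in all 5 lists leaves open how reads of the sex chromosomes were handled.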
